A study of Mus musculus with 20 samples.

How the data were processed

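ATAC-seq libraries were made from sorted Lrig1 GL, Sca1-positive epidermal cells of mice, per the labels' protocols: the cells were collected into lysis buffer, their DNA was cut by Tn5 transposase and the libraries were indexed with Nextera XT primers. The 20 libraries form 10 groups of 2 by the treatment that the labels give. The genome build is mm10, per the submitters' processing notes. The aligner, the peak caller, the filters, the read depth and any shift of the reads for Tn5 are not given in the sources used here. Whether animals or only libraries differ between the 2 replicates of a group is not given either.

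The deposited data are 10 peak lists, 1 per group, each made by the authors from both libraries of its group. They keep peaks that pass a reproducibility threshold between replicates, as far as the names of the lists tell, so a peak in only 1 of the libraries is not expected in them. Each list gives, per peak, the authors' score, which was 540 or higher in every list, the authors' signal value of enrichment, which is used here to rank and filter regions within a list, and the authors' −log10 p of the peak, which was 2.00 or higher. The deposited summit offset gave the position used for annotation. No list holds values per library. Replicates could therefore not be compared, no test between groups was possible, and intervals cover counting error only. They are Wilson 95% intervals for shares of regions, and exact binomial 95% intervals for ratios to mirrored sets and for shares among regions held by 1 of the UVB lists alone.

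Several peaks of a list often share 1 interval, so overlapping peaks were merged into regions on chromosomes 1 to 19, X and Y, and the strongest peak gave a region its signal value and summit. A region of a list with no overlap of at least 1 bp with any region of the other list was counted as gained or lost. The overlap counts were compared with bedtools 2.31.1, and all 14 counts checked were equal. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The code was tested on simulated data: in the homeostasis list with 3000 regions removed and 5000 added, 3000 lost and 5000 gained regions were found. Of 200 random gene lists, 10 lay outside the central 95%, and all 20 lists of 20 genes with 30% of their shared regions moved to gained were found.

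Genes were taken from the reference table for GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes. As a check of the build, the summits lay within 1 kb of a gene end for 18.3 to 28.9% of the regions of a list, against 5.02 to 5.38% after a shift by 100 kb. The table gives gene spans without strand or exons, so the plan to use transcription start sites was changed. A region belongs to the shortest protein-coding gene that contains its summit, or else to the gene with the nearest end within 100 kb, and the window of 1 kb was laid around both ends of a gene. Exons, introns and UTRs were not separated. The planned search for 20 transcription factor motifs was not run, since no genome sequence was used here.

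For each of 23 gene lists fixed before the data were examined, the balance is gained minus lost regions as a share of all regions of its members. Of the 405 genes on the lists, 403 were found. The percentile of the balance among 10000 random lists, matched on each member's number of regions, is a description of these lists of peaks. A list counts as outside below percentile 2.5 or above 97.5. Neighbouring genes on a list, such as Hox genes, are not independent, and comparisons with the same homeostasis list share its chance values. For the overlap between comparisons with the same homeostasis list, 100 sets of lists were drawn without any effect. Each list was drawn independently, at its own rate among regions held by the same number of the 6 other groups.

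Named genes followed a rule fixed before the data were examined. In each comparison except the second wound against homeostasis, these are the 6 genes with the highest and the 6 with the lowest gained minus lost, with ties broken by signal value and predicted genes left out, the member with the largest balance of each gene list (3 members for a list outside the central 95%), and the 3 strongest gained and lost regions. The text gives most of these and leaves out list members with small balances. For a single gene, balance means the count of gained minus lost regions, not a share of its regions. For a list member the largest balance is the largest in size, whether gained or lost. Alternatives were an overlap of at least 50% of both regions, the strongest 50% of each list, lists of equal length, strong regions that the whole other list lacks, vehicle as the control, genes within 20 kb and a window of 500 bp. Analyses of Y-linked genes, mirrored sets, short strong regions, and UVB and cultured cells against vehicle were chosen after the data were seen.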

Results

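Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in epidermal cells of Lrig1CreER/Rosa-TdTomato mice. In such mice, once Cre is activated, a red fluorescent protein marks cells that express Lrig1, a regulator of receptor tyrosine kinases found in the upper hair follicle, and their descendants. The sorted cells are named Lrig1 GL and Sca1-positive; Sca1 is a surface protein encoded by Ly6a. The labels give 20 libraries in 10 groups of 2: homeostasis, 1 week and 8 weeks after the first wound, 1 week after the second wound, vehicle, PRT4165, UVB, wound with UVB, and cells cultured from a control and from a distal memory region 8 weeks after the first wound. PRT4165 inhibits the histone H2A ubiquitin ligase activity of Polycomb repressive complex PRC1. Each group has 1 list of peaks made from both of its libraries, so no value below has a spread between replicates and no difference was tested for significance.

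The lists held between 34644 regions (8 weeks) and 73340 regions (UVB). The homeostasis list held 35195, the 1-week list 49078, the second-wound list 42200, the vehicle list 70008, the PRT4165 list 68411, the wound-and-UVB list 66541, the cultured control list 54188 and the cultured distal list 45714. The read depth of the libraries is not given in the sources used here. The region with the highest −log10 p was the same in every list, on chromosome 2 from 69355469, and its value was 5196 in homeostasis, 6093 at 1 week, 5503 after the second wound and 5723 at 8 weeks. It was 11009 with vehicle, 11234 with PRT4165, 9542 with UVB, 7592 with wound and UVB, 10413 in the cultured control and 10960 in the cultured distal list. Gained below means present in the first-named list with no overlap in the other, and lost the reverse. Both counts move with the lengths of the lists. Genes were assigned by position, so a region near a gene is not evidence that it controls that gene.

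Genes that mark keratinocytes and the sorted lineage were looked up in each list. A region lay within 1 kb of an end of Lrig1, Ly6a, Krt14, Krt5 and Krt6a in all 10 lists. For Krt10, a keratin of the differentiating layers, such a region was present in 6 lists and absent from the 4 lists of homeostasis and the wound time course. For Trp63, the master regulator of stratified epithelium, it was present only in the vehicle list. Only the ends of the gene span were searched, so this does not mean that Trp63 lacks open regions elsewhere. The 8-week and homeostasis lists shared 9 regions assigned to it. Genes of the p53 and DNA damage response carried such a region for 22 of 23 members in every list, and the AP-1 and immediate early list for 17 to 19 of 19 members. The developmental regulators, textbook Polycomb targets such as Hox and neural fate genes, had one for 10 of 47 members in homeostasis, 18 at 1 week, 6 at 8 weeks, 8 after the second wound and 25 with vehicle.

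The lists also differed in the Y chromosome. Regions at the ends of Ddx3y, Uty and Eif2s3y, Y-linked genes expressed in most male tissues, were present in 5 lists: 1 week after the first wound, 1 week after the second wound, wound with UVB, and both cultured lists. They were absent from the other 5: homeostasis, 8 weeks, vehicle, PRT4165 and UVB. Where present, their signal values ran from 14.8 to 25.4, above those of at least 86.7% of the regions of the same list. The Y-linked Kdm5d had no region at its ends in any list. Xist, which is transcribed from the inactive X chromosome of female cells, had a region in 7 lists, among them the 1-week and wound-and-UVB lists that also hold the Y-linked regions. It had none in the second-wound list and both cultured lists. The labels do not give the sex of the animals. These genes were chosen after their values were seen. The comparisons of 1 week or the second wound with homeostasis, and of wound with UVB against UVB, therefore set lists with these Y-linked regions against lists without them. The other 4 comparisons do not.

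**Figure D1:**
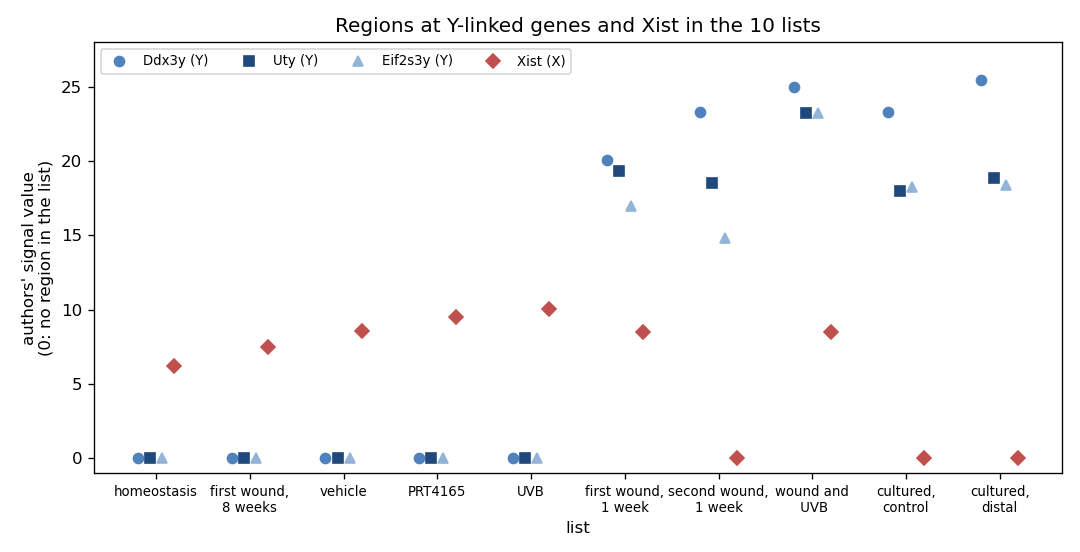
The authors' signal value of the strongest region at the ends of Ddx3y, Uty and Eif2s3y and over Xist (vertical axis, no unit, 0 where the list holds no region) in each of the 10 lists (horizontal axis), 1 value per list and no error bars. The 3 Y-linked genes have regions in 5 lists, from 14.8 to 25.4, and in none of the other 5. Values are each list's own and heights are not compared between lists.

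The first comparison asked what opens or closes in these cells 1 week after a wound. Compared with homeostasis, 16261 regions were gained (33.1% of the 1-week list, 95% interval 32.7 to 33.6%) and 2125 were lost (6.04% of the homeostasis list, 5.79 to 6.29%), with 32817 shared. Gained minus lost was highest at Rad51b, a DNA repair gene (21 gained, 3 lost), Macrod2 (18 and 1) and the Wnt5a receptor Ror2 (16 and 0). The ranking is by count and favours genes with many regions: Rad51b also had 30 shared regions and Macrod2 28, while Ror2 had 6. Next came the neurotrophin receptor Ntrk2 (16 and 0), Lrmda (14 and 0) and Tenm4 (14 and 0). The balance was lowest at Mtap (1 gained, 4 lost), Alk (2 and 4), Kcnh5, Skint11, Ermp1 and Gda (each 0 and 2). Developmental regulators gained 32 regions and lost 3, led by Neurod1 (5 gained, 0 lost), Hoxb9 (3 and 0) and Hoxb1 (3 and 1), and their balance lay at percentile 99.2 of random gene lists. The p53 and DNA damage response list gained 16 and lost 10, at percentile 0.01. In that list the stress sensor Gadd45b gained 4 and Cdkn1a, the p21 cell cycle inhibitor, gained 2, while the pro-apoptotic Pmaip1 lost 2 and gained 0.

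Of the 6 lists of markers of other cell types, 2 lay outside the central 95% in the same comparison. Fibroblast markers gained 11 regions and lost 0 (percentile 99.3), with Dcn and Dpt at 3 each and Col1a1 at 2, and T cell markers gained 9 and lost 0 (percentile 98.1), with Cd2 at 5, Cd247 at 2 and Cd27 at 1. The other 19 lists lay between percentile 2.74, the wound-activated keratinocyte genes (15 gained, 4 lost), and percentile 88.0, the Wnt pathway (44 gained, 3 lost). AP-1 and immediate early genes gained 30 and lost 3 (percentile 4.09), but lay outside the central 95% with genes within 20 kb (percentile 0.73) and at equal length, as did the interfollicular basal layer at equal length (1.31). Single members of the remaining lists with the largest balance were Fst (5 gained) in the upper follicle list, the stem cell receptor Lgr6 (6) in the bulge list, Tgm3 (8) in epidermal differentiation, Acsbg1 (5) in the sebaceous gland, Ptgs2 (3), the prostaglandin synthase, among wound-activated genes, Jun (5), the alarmin Il33 (6), Egln3 (5) in glycolysis and hypoxia, and Smad3 (9) in the TGF-beta list. The strongest gained region lay within Mbtd1 (chromosome 11, 93940799 to 93941441, mm10, signal value 23.2) and the strongest lost region within Plxdc2 (chromosome 2, 16683005 to 16683213, signal value 31.2). Of the gained regions 9.78% (9.34 to 10.3%) lay within 1 kb of a gene end, against 29.8% of the shared regions (29.3 to 30.3%). The gained regions were also weaker, with a median signal value of 7.16 against 10.3. With both lists limited to their 35195 strongest regions, which makes the 2 counts nearly equal by construction, 8415 regions were gained and 8030 lost. In that setting the developmental regulators lay at percentile 78.9 and the T cell markers at 80.5. The p53 list again lay at 0.01 but then had 6 gained and 30 lost, so its net direction turned. Fibroblast markers lay at 97.4 with genes within 20 kb. With vehicle in place of homeostasis, 2441 were gained and 23209 lost. The 1-week list holds the Y-linked regions and the homeostasis list does not.

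**Figure D2:**
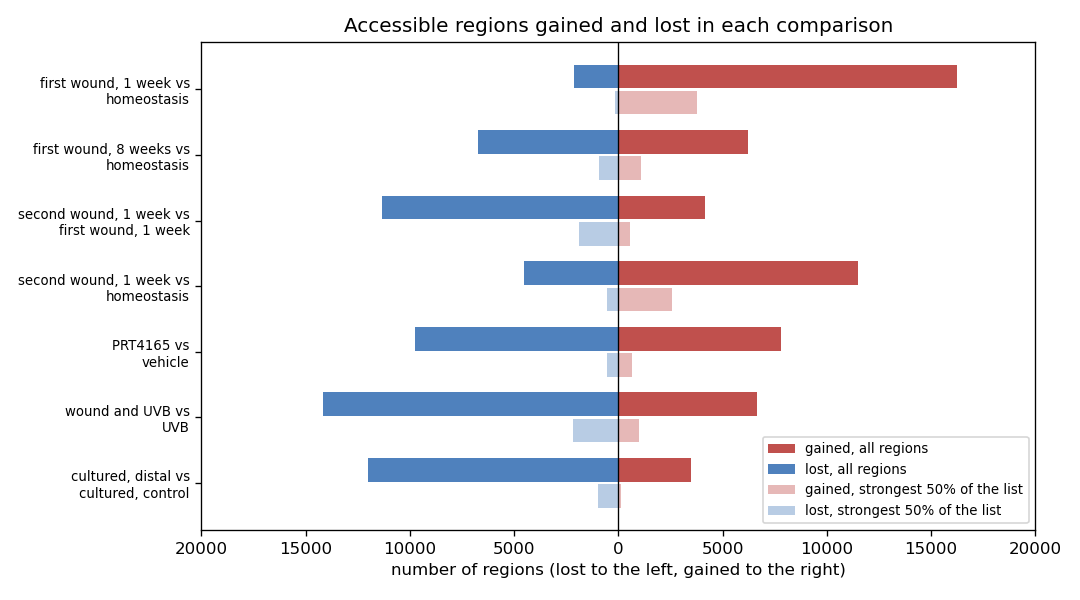
Number of regions gained (right of 0) and lost (left of 0) in each of the 7 comparisons (rows). Dark bars count all regions and light bars those in the strongest 50% of their own list by signal value that the whole other list lacks. Bars are counts from 1 list per group, with no error. The 1-week list gained 16261 and lost 2125 over homeostasis, and the 8-week list gained 6195 and lost 6712.

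Whether accessibility stays altered long after healing was addressed at 8 weeks. Genes of the interfollicular basal layer gained 7 regions and lost 23 against homeostasis, at percentile 0.51 of random lists: Trp63 had 1 gained and 5 lost, the hemidesmosome linker Dst 2 and 5, and the hemidesmosomal collagen Col17a1 0 and 3. The balance of the p53 and DNA damage response list again lay below most random lists (7 gained, 20 lost, percentile 0.78), with Gadd45g at 0 and 3, the death receptor Fas at 1 and 3 and Pmaip1 at 0 and 2. Endothelial markers had 5 gained and 12 lost (percentile 0.92; Cdh5 0 and 3, Pecam1 3 and 4, Cldn5 0 and 1), and fibroblast markers 4 gained and 0 lost (percentile 98.4; Dcn 2 gained, Col1a1 and Dpt 1 each). In total 6195 regions were gained (17.9%, 17.5 to 18.3%) and 6712 lost (19.1%, 18.7 to 19.5%), with 28449 shared.

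By gene, the 8-week balance was highest at Tbc1d1 (8 gained, 2 lost), Arhgef28 (9 and 3), Cpne8, Kalrn, Farp1 and Zbtb20 (each 5 and 0). It was lowest at the growth factor receptor Igf1r (1 and 8), the Wnt ligand Wnt10a (0 and 6), Eml4 (1 and 7), Dlg2 (0 and 5), Irf2bpl (1 and 6) and Rad51b (6 and 11). Lrig1 itself had 0 gained, 4 lost and 8 shared regions. The other 19 lists lay between percentile 5.21 (wound-activated keratinocyte genes, 5 gained and 13 lost, Tnc 0 and 3) and 95.7 (cell cycle, 5 gained and 0 lost, Cdk1 1 and 0). Members of lists inside that range included the follicle keratin Krt75 (4 gained), Tgm3 (3 gained, 6 lost), Prdm1 (0 and 3), Egr3 (0 and 2), Il17ra (2 gained), Ddx58 (0 and 2), Hk2 (3 gained), Tgfb2 (0 and 4) and Fgfr2 (2 and 5). The strongest gained region was again within Mbtd1 (signal value 21.4), and the strongest lost region lay within Zfp949 (chromosome 9, 88553168 to 88553376, signal value 26.5). With regions assigned only to genes within 20 kb, the p53 list lay at percentile 7.74, fibroblast markers at 91.7 and endothelial markers at 8.04, all inside the central 95%, and the Wnt pathway at 1.82, outside it.

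Of the 16261 regions gained at 1 week, 4835 (29.7%, 29.0 to 30.4%) were in the 8-week list. Counted over merged regions, 4666 were gained at both times, against 1395 for independent lists of these sizes. In 100 sets of lists drawn without any effect from regions equally common in the 6 other groups, the mean was 8407 (8165 to 8598). Each list was drawn independently there, while the real 1-week list held 94.0% of the homeostasis regions. The draws were not made to keep that overlap or the numbers gained, so the count cannot be judged against them. The homeostasis list is shared by both comparisons and could not be split. The vehicle list, whose labels name no wound, held 86.1% (85.5 to 86.6%) of the regions gained at 1 week, 93.8% (93.2 to 94.4%) of those gained at 8 weeks and 6374 of the 6712 lost at 8 weeks. Of the 2266 regions gained at 1 week that vehicle also lacked, 174 (7.68%, 6.65 to 8.85%) were in the 8-week list.

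The response to the second wound was set against the response to the first at the same time after wounding. Developmental regulators had 4 gained and 26 lost regions (percentile 0.30), led by Neurod1 (0 and 5), Lhx5 (0 and 2) and the kidney and gonad regulator Wt1 (0 and 1), so that 18 of the 47 members lost more than they gained and 1 gained more. T cell markers had 0 gained and 8 lost (percentile 0.34; Cd2 0 and 4, Cd247 0 and 2, Cd27 0 and 1). Both lists also stayed outside the central 95% with the lists limited to equal length and with genes within 20 kb. The same 1-week list gave both their high values against homeostasis, so a chance excess in it would give both results. For the second wound against homeostasis, developmental regulators lay at percentile 53.5 and T cell markers at 39.5. In total 4155 regions were gained (9.85%, 9.57 to 10.1%) and 11331 lost (23.1%, 22.7 to 23.5%), with 38045 shared.

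Between the first and the second wound the largest gene balances were at Ppp2r2c (7 gained, 0 lost), the axon guidance gene Sema5a (6 and 2), B3gnt7, Paqr5 and Ap3s2 (each 3 and 0) and Sae1 (4 and 1). The lowest were Macrod2 (4 and 15), Rad51b (5 and 16), Tbc1d1 (0 and 10), Zbtb7c (2 and 12), Ror2 (1 and 11) and Prkce (2 and 11). The other 21 lists lay between percentile 3.13 (Wnt pathway, 5 gained and 31 lost, Sfrp1 1 and 6) and 92.2 (glycolysis and hypoxia, 8 and 16, Hk2 1 and 4). Lrig1 had 1 gained and 4 lost, Nfatc1 0 and 4, Dst 1 and 7, Tgm3 2 and 10, Myc 0 and 3, the cytokine gene Il1a 0 and 4, Smad7 0 and 6 and Fgfr2 2 and 9. The 3 strongest gained regions were under 300 bp wide and lay within Plxdc2 (signal value 51.7), within Zfp949 (46.0) and near Sulf1 (45.9). With both lists limited to 42200 regions, 7585 were gained and 7989 lost, and AP-1 genes moved from percentile 86.8 to outside the central 95% on the high side. With genes within 20 kb the Wnt pathway lay at 0.40 and Merkel cell markers at 1.30. At equal length the Merkel cell markers were also outside, while the Wnt pathway lay on the other side of the median, at 68.5.

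The second-wound list was also compared with homeostasis, with 11512 regions gained (27.3%, 26.9 to 27.7%) and 4534 lost (12.9%, 12.5 to 13.2%). Wound-activated keratinocyte genes gained 7 regions and lost 10, at percentile 0.40 of random lists. The p53 and DNA damage response list gained 14 and lost 12 (percentile 1.73, and 11.5 with genes within 20 kb), and fibroblast markers gained 8 and lost 0 (percentile 99.2, and 90.1 at equal length). The other 20 lists lay between percentile 4.43, the interfollicular basal layer, and 96.0, the bulge and lower follicle. At equal length 2 of these were outside the central 95%, AP-1 genes below all 10000 random lists and epidermal differentiation at 1.23. Of the regions gained 1 week after the first wound, 8061 (49.6%, 48.8 to 50.3%) were present 1 week after the second. Over merged regions the number gained after both wounds was 7837, against 2610 for independent lists. The mean was 10451 (10226 to 10659) in the lists drawn without any effect, which again cannot serve as a level to judge the count against. Of the 2266 that vehicle also lacked, 647 (28.6%, 26.7 to 30.4%) were present after the second wound. Vehicle in place of homeostasis gave 1686 gained and 29679 lost, and equal length gave 8174 and 8000. The second-wound list, unlike the homeostasis list, holds the Y-linked regions.

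PRT4165 was compared with its vehicle to ask what opens or closes with this inhibitor of PRC1 ligase activity. The data used here do not measure that activity. Genes of the bulge and lower follicle, the stem cell compartment below the upper follicle, gained 11 regions and lost 35, at percentile 0.72. The bulge quiescence factor Nfatc1 had 0 gained and 7 lost, the Wnt effector Tcf7l2 2 and 7 and Lgr6 1 and 6. Developmental regulators, the textbook Polycomb targets, gained 12 and lost 25 (percentile 3.33), with 5 members gaining more and 15 losing more, among them the muscle regulator Pax7 (0 and 3). Their balance lay at percentile 1.90 at equal length, outside the central 95%, and at 12.8 with genes within 20 kb, inside it. Polycomb subunits and H2A deubiquitinases gained 10 and lost 15 (percentile 36.7; Pcgf5 1 and 3). Melanocyte markers gained 5 and lost 1 (percentile 97.8; Dct and Tyrp1 1 gained each, Mitf 2 and 1), but lay at 96.3 at equal length and 89.9 with genes within 20 kb. Fibroblast markers lay inside the central 95% (22.1) but at 1.48 with genes within 20 kb.

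In total 7784 regions were gained with PRT4165 (11.4%, 11.1 to 11.6%) and 9736 lost (13.9%, 13.7 to 14.2%), with 60627 shared. The largest balances were at the potassium channel gene Kcnk2 (7 gained, 0 lost), Fmn1 (8 and 1), Nckap5 (8 and 2), Syt1, Abhd5 and Cdc7 (each 6 and 0). The lowest were at Rad51b (4 and 20), Zmiz1 (2 and 13), the Notch coactivator Maml3 (1 and 11), Edn1, which encodes endothelin-1 (0 and 8), Adgrl2 (2 and 10) and Ppargc1b (0 and 8). Named members of other lists were Plet1 (4 gained), Itga6 (0 and 4), Tgm3 (1 and 8), Fos (0 and 4), Nfkbiz (0 and 3), Pfkp (0 and 4), Zeb2 (0 and 3), Notch1 (0 and 3) and Fzd7 (1 and 6). The strongest gained region lay within Serpina3j (signal value 21.9) and the strongest lost region within B3galt1 (16.2). Regions gained at 8 weeks over homeostasis made up 3.26% (2.89 to 3.68%) of the regions gained with PRT4165, against 9.94% of the shared regions of the same width. They made up 1.61% (1.33 to 1.94%) of those gained with wound and UVB over UVB, against 9.88%, and 5.38% (4.68 to 6.19%) of those gained in the cultured distal list, against 5.93%. The first 2 gaps follow largely by construction, since gained regions are absent from the vehicle or UVB list, and these lists held 93.8% and 96.1% of the 8-week regions; the cultured control list held 44.8%. Of the 6195 regions gained at 8 weeks, the PRT4165 list held 5767 and vehicle 5814, wound with UVB 5537 and UVB 5952, and the cultured distal list 2371 and its control 2775.

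The effect of wounding in UVB-treated skin was read from the wound-and-UVB list against the UVB list. AP-1 and immediate early genes, the early transcriptional response to stress, gained 24 regions and lost 20, at percentile 99.6 of random lists, with 9 members gaining more and 4 losing more. The members with the largest balance, however, lost regions: Jun had 1 gained and 4 lost and Klf4 1 and 4, while Myc had 2 gained and 0 lost. Melanocyte markers had 0 gained and 11 lost (percentile 0.64), led by the pigment cell antigen Mlana (0 and 4), Mitf (0 and 3) and Dct (0 and 2). Fibroblast markers had 0 gained and 10 lost (percentile 1.45; Dpt, Pdgfra and Col6a1 0 and 3 each), a value that lay at percentile 17.0 at equal length and 6.13 with genes within 20 kb. In total 6661 of 66541 regions were gained (interval 9.78 to 10.2%) and 14169 of 73340 lost (19.3%), with 59880 shared. The wound-and-UVB list holds the Y-linked regions and the UVB list does not.

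In UVB-treated skin the largest gene balances were at Foxp1 (13 gained, 5 lost), Auts2 (13 and 6), the TGF-beta co-receptor Tgfbr3 (9 and 2), Mcc (8 and 2), and Pja1 and Tox3 (each 5 and 0). The lowest were at Pde4d (1 and 15), Arl15 (0 and 13), Snd1, Arid1b and Rgs3 (each 0 and 11) and Fmn1 (0 and 10). The strongest gained regions lay near the cornified envelope gene Lce3e (chromosome 3, 92978524 to 92978841, signal value 26.7) and near Pja1 (chromosome X, 99504104 to 99504820, 26.5). The other 20 lists lay between percentile 11.5 (Langerhans and myeloid markers, 0 gained and 5 lost, H2-Eb1 0 and 2) and 92.6 (epidermal inflammation, 16 and 20, Nfkbia 0 and 3). Other named members were Tcf7l2 (0 and 8), Krt5 (0 and 3), Casp14 (0 and 4), Elovl4 (1 and 7), the EGFR ligand Areg (4 and 1), Jarid2 (1 and 6), Met (0 and 7) and Lef1 (0 and 6). With both lists limited to 66541 regions, 10443 were gained and 11238 lost, and AP-1 genes had 46 gained and 8 lost, outside the central 95% on the high side. They also lay high at equal length for the second wound over the first and for the cultured distal list. In those the first-named list is shorter too. For the second wound against homeostasis, where it is longer, they lay low. This setting thus followed list length for AP-1 genes and is no separate support. At equal length the p53 list (99.4) and epidermal differentiation (99.2) were outside as well.

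The last comparison set cells grown from the distal memory region against cells grown from the control region. The upper follicle and Lrig1 lineage list had 2 gained and 23 lost regions in the distal list, at percentile 1.48: Lrig1 had 0 gained and 6 lost, Plet1 0 and 5 and the aquaporin gene Aqp3 0 and 3. At equal length this list lay at percentile 33.6. Genes of the bulge and lower follicle had a balance above the central 95% of random lists (13 gained, 19 lost, percentile 97.7), although Lgr5 had 1 gained and 5 lost, Sox9 0 and 2 and Tcf7l2 2 and 3. The balance of AP-1 and immediate early genes was also high (5 gained, 13 lost, percentile 98.4), with Klf6 at 2 and 4, Myc at 0 and 2 and Fos at 0 and 1. It lay at 77.7 with genes within 20 kb. At equal length, a setting that followed list length for these genes, they had 28 gained and 4 lost (percentile 99.98). In total 3473 regions were gained (7.60%, 7.36 to 7.84%) and 12005 lost (22.2%, 21.8 to 22.5%), with 42241 shared.

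In the cultured distal list the largest gene balances were at Osbpl8 (4 gained, 0 lost) and, with 3 gained and 0 lost each, Stx7, Cracd, Podxl, Prkx and the desmosome gene Dsp. The lowest were at Nedd4l (0 and 13), Macrod2 (2 and 13), Robo2 (1 and 11), Etl4 (2 and 12), Pdzd2 (0 and 9) and Trim2 (0 and 9). The other 20 lists lay between percentile 2.68 (melanocyte markers, 0 gained and 8 lost, Tyrp1 0 and 3) and 89.9 (epidermal inflammation, 7 and 17, Ccl20 0 and 2). Named members of those lists were Dst (0 and 5), Grhl3 (0 and 3), Pparg (0 and 3), Ptgs2 (0 and 4), Rybp (0 and 6), Tgfbr2 (0 and 6), Met (0 and 6) and Wnt7b (0 and 7). The strongest gained region lay within Pla2g4c (signal value 13.5) and the strongest lost region near Mbd2 (17.3). With both lists limited to 45714 regions, 7069 were gained and 7334 lost, and melanocyte (2.05) and T cell markers (97.6) lay outside the central 95%.

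Across the 7 comparisons, 21 of the 161 gene list percentiles lay outside the central 95% of random lists, where 8.05 would by chance. Of the 21, 9 lay above and 12 below. Both alternatives, genes within 20 kb and lists of equal length, left 9 of the 21 outside on the same side. Equal length is no separate support for AP-1 genes, which moved there with list length. The p53 list moved likewise in UVB-treated skin. At 1 week its percentile stayed at 0.01, while its counts went from 16 gained and 10 lost to 6 and 30. In each of the 7 comparisons the gained and lost regions lay less often within 1 kb of a gene end than the shared regions did. They were also weaker in each. With PRT4165 the median signal value was 6.44 for gained, 5.85 for lost and 10.1 for shared regions. Whether this weakness accounts for the difference in location was not tested. With PRT4165 the shares were 6.91% of gained, 9.33% of lost (8.76 to 9.92%) and 20.1% of shared regions (19.8 to 20.4%).

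**Figure D3:**
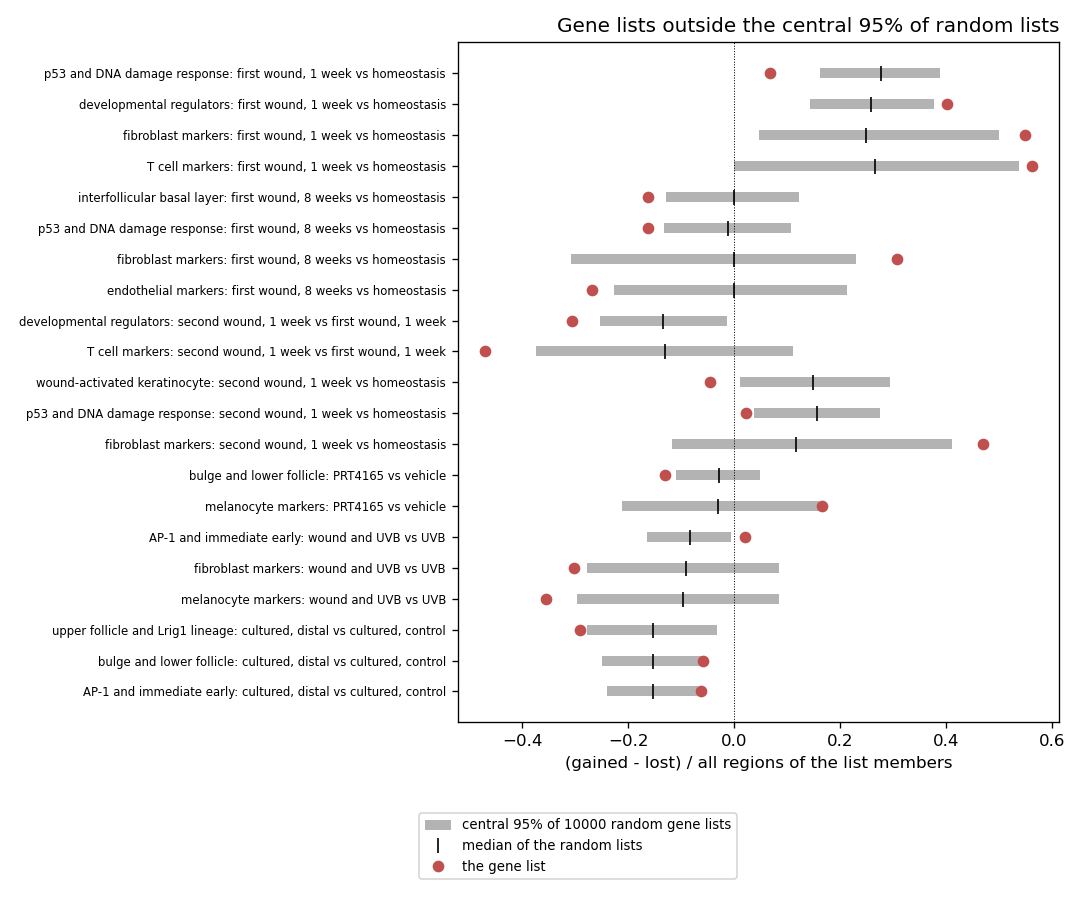
Balance of each gene list outside the central 95% of random lists (dots; gained minus lost regions, as a share of all regions of its members, no unit), with the median (tick) and central 95% (grey bar) of 10000 random lists matched on the number of regions per gene. Rows name the gene list and the comparison, 1 list of peaks per group. The 21 dots lie outside their bars, 9 above and 12 below, where 8.05 of 161 would by chance.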

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

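In total 16 tests of explanations were run on 3 patterns, 7 set out before their results were seen and 9 after. Those chosen after were the ratio to the mirrored set as deposited and among regions that vehicle lacks, the share held by the PRT4165 list, set against both sex and an opening that needs a wound, the cultured share of regions that PRT4165 lacks, list length for the UVB lists, the sex test on 8-week regions, and both tests of a state left by the earlier wound. So was the choice to keep the regions of vehicle in for the ratio of the second pattern. Gained minus lost regions had opposite signs in a pair of comparisons: 14136 at 1 week against homeostasis and -7508 for wound with UVB against UVB. Gained minus lost nearly equals the difference in list length by construction. The 1-week list is longer than homeostasis (49078 and 35195 regions), and the wound-and-UVB list shorter than the UVB list (66541 and 73340). The signs thus follow list length, and why the lengths differ was not tested. The first sign turned with vehicle in place of homeostasis (2441 gained, 23209 lost), while at equal length the counts were nearly equal by construction (8415 and 8030). Fibroblast markers also went opposite ways, with a balance of 0.55 without UVB and -0.303 with it. Each value comes from 1 list per group and the differences were not tested. No group has enough samples for a search for outlying samples.

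The first pattern is that the vehicle list held 93.8% of the regions gained at 8 weeks. Regions in the 1-week and 8-week lists but not in homeostasis numbered 4666, and the mirrored set, in homeostasis and at 1 week but not at 8 weeks, 4870, a ratio of 0.958 (95% interval 0.920 to 0.998). At equal list length the ratio was 1.03, below the bound of 1.5 set for a lasting opening. The set was thus about as large as its mirror, as regions near the calling threshold that the short homeostasis list missed would give. A lasting opening beside a like number of closures would give the same ratio, so the test does not decide between them. Among regions that vehicle lacks, the ratio was 1.31 (1.03 to 1.67), and 1.79 (1.26 to 2.56) at equal length. Vehicle held nearly the same share of both lists that define the sets, 98.9% of homeostasis and 98.7% of the 8-week list. Without the regions of PRT4165 as well, the ratio was 0.970 (0.577 to 1.63) and 1.45 (0.634 to 3.47). For these a lasting opening and chance near the threshold cannot be told apart, since all these intervals span the bound.

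The second pattern is a set of 620 regions, called wound regions below, present 1 week after both wounds and in neither homeostasis nor vehicle, against 85 in the mirrored set (in homeostasis and at 1 week, in neither the second-wound nor the vehicle list); with the regions of vehicle kept in, the sets hold 7837 and 2945. At equal length, with the regions of vehicle kept in, the ratio was 2.05 (1.95 to 2.16), above the bound of 1.5. That cut to 34644 regions removed weak regions mainly from the 1-week and second-wound lists (49078 and 42200), and few from homeostasis (35195). The ratio therefore cannot settle whether longer lists after wounding gave the pattern. Without the regions of vehicle the ratio at equal length was 8.94. That filter raises it, since vehicle held 98.9% of the homeostasis list but 96.0% of the second-wound list. Short regions of a technical kind are argued against by a share of 2.42% under 300 bp. The pooled markers of 5 other cell types had 0 wound regions (percentile 14.6, or 1 region and 52.1 with Merkel cell markers), which decides nothing. The PRT4165 list lacks the Y-linked regions and its labels name no wound. It held 48.9% (45.0 to 52.8%) of the set, and the UVB list, of the same kind, 61.1%. The sex of the animals is a candidate explanation, since the lists differ in the Y-linked regions. These shares argue alike against sex and against an opening that needs a wound, each as the source of every region. Yet the PRT4165 list held more of the mirrored set, 72.9% (62.7 to 81.2%). Either explanation would give that for part of the wound regions. The cultured lists have the Y-linked regions but held 19.8% (16.9 to 23.2%) of the set and 41.2% (31.3 to 51.8%) of the mirrored set. Of the regions that PRT4165 lacks, they held 14.8% (11.3 to 19.2%) of 317 and 43.5% (25.6 to 63.2%) of 23. These lower shares are the reverse of what sex would give but cannot decide on it. The cultured control list also held fewer of the regions gained at 8 weeks over homeostasis (44.8%) than of those lost (52.8%). Neither the 8-week nor the homeostasis list has the Y-linked regions. Opening 1 week after a wound met the bound of 1.5 set for it beforehand, with a lower bound of 1.95. It stays open as a hypothesis, because the share held without a named wound goes against it, and list length and other cell types are undecided. Sex is undecided too, beyond not being the source of every region.

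The third pattern is that the wound-and-UVB list held 492 of the wound regions and the UVB list 379, and of those held by 1 of these lists alone, 72.0% (66.1 to 77.4%) were in the wound-and-UVB list, the shorter. Among 29900 other regions outside the controls the share was 36.4% (35.4 to 37.3%), where the longer list held more. The excess in the wound regions was thus not found in these other regions. The longer UVB list lowers such a share whatever the likeness, and over all regions it was 32.0% (31.4 to 32.7%). The test therefore cannot decide on a general likeness to regions outside the controls. List length alone would favour the longer list, so it would act against the pattern. For length the outcome of this test was fixed in advance. The lower bound of 66.1% restates the pattern and does not decide on a state left by the earlier wound, since the labels give no time after that wound. Among regions of the 8-week list outside homeostasis and vehicle the share was 14.9%, with an upper bound of 23.3%. The sex of the animals would lower it, since the 8-week and UVB lists lack the Y-linked regions and the wound-and-UVB list has them. The longer UVB list would lower it too, although it was below the 36.4% of the other regions. This low share thus cannot decide on sex, and it cannot count against a state left by the wound. Sex stays a hypothesis for this pattern because the lists differ in the Y-linked regions. It is argued against as the source of every wound region. The wound-and-UVB list also holds a region over Xist. A state left by the wound, lasting or short-lived, stays open as well.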

How the results depend on the processing

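Leaving out X and Y and the comparison with mirrored sets were chosen after the results were seen. No paired analysis was possible because each list was made from both libraries of its group. Leaving out a replicate could not be run for the same reason, and the motif search was not run. Read depth is not given in the sources used here, so its effect on list length could not be measured. Without X and Y, all 14 counts of gained and lost regions stayed within 1.5 times, and with 50% reciprocal overlap 14 of 16 counts did.

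Reciprocal overlap gave 4015 lost regions at 1 week and 5250 gained in the cultured distal list. At equal list length, where gained and lost are nearly equal by construction, the counts that moved by over 1.5 times were 8415 gained and 8030 lost at 1 week, 7585 gained after the second wound over the first, 8000 lost after the second wound against homeostasis, 10443 gained with wound and UVB, and 7069 gained and 7334 lost in the cultured distal list. With vehicle in place of homeostasis, gained and lost were 2441 and 23209 at 1 week, 442 and 35932 at 8 weeks and 1686 and 29679 after the second wound; the cause was not tested. Requiring absence from vehicle too left 174 regions present at 8 weeks and 647 after the second wound, fewer by construction.

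Both filters on strength shorten the lists, so lower counts follow by construction. With the strongest 50% of each list, gained and lost were 8362 and 1407 at 1 week, 3183 and 3462 at 8 weeks, 2427 and 5884 for the second wound over the first, 6004 and 2517 for the second wound against homeostasis, 3347 and 4172 with PRT4165, 3315 and 6762 with wound and UVB, and 1072 and 5282 in the cultured distal list. Of the regions gained at 1 week, 2308 were then present at 8 weeks and 4060 after the second wound. Counting strong regions absent from the whole other list, they were 3757 and 167, 1082 and 911, 549 and 1904, 2594 and 523, 654 and 570, 1008 and 2163, and 133 and 974, in the same order of comparisons. Gained then outnumbered lost at 8 weeks and with PRT4165, the reverse of the full lists; the cause was not tested.

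Of the 35 gene list percentiles outside the central 95% in any setting, genes within 20 kb brought 8 inside and put 5 outside, and equal length brought 6 inside and put 11 outside.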

Other observations

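All comparisons in this part were chosen after the results were seen, as were the genes named. Cells in culture were set against fresh vehicle cells, with 16894 regions gained (31.2%) and 32664 lost (46.7%). Epidermal differentiation genes gained 9 and lost 81 regions, a balance below all 10000 random lists, led by the transglutaminase Tgm3 (1 gained, 20 lost). Genes of the bulge and lower follicle gained 23 and lost 107 (percentile 0.29), with Nfatc1 at 0 and 25. Wound-activated keratinocyte genes went the other way, with 50 gained and 36 lost (percentile 99.95), among them the collagenase Mmp13 (5 and 0) and Ptgs2 (8 and 2), and the TGF-beta list had 40 gained and 48 lost (percentile 98.6). Fibroblast markers gained 5 and lost 20 (percentile 2.23). The cultured control list holds the Y-linked regions and the vehicle list does not, and culture, region of skin, wounding and sex were not separated.

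UVB was set against vehicle, lists that both lack the Y-linked regions, with 11862 regions gained (16.2%) and 8108 lost (11.6%). Melanocyte markers gained 10 and lost 0 (percentile 99.8): Mitf, the master regulator of pigment cells, gained 4, Mlana 3, and Pmel, Dct and Tyrp1 1 each. The p53 and DNA damage response list gained 17 and lost 9 (percentile 58.6). The other 22 lists lay inside the central 95%. Gained minus lost was highest at Rora (18 gained, 4 lost) and Kcnk2 (12 and 0).

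The 620 wound regions lay near 536 genes, 6.94% of them (5.19 to 9.21%) within 1 kb of a gene end, with a median width of 659 bp. The strongest in the 1-week list were at Ddx3y, Uty and Cacul1 (signal values 20.1, 19.3 and 17.9), and 9 lay on X or Y. For the share of regions that were wound regions, all 23 gene lists lay inside the central 95% of random lists, from percentile 13.3 (Wnt pathway) to 96.1 (p53 and DNA damage response), with the AP-1 list at 91.9 and the wound-activated keratinocyte list, which had 0 wound regions, at 18.1. Spdl1 and Kalrn had 3 wound regions each.

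Regions under 300 bp wide with a signal value above 20 numbered 52 in the second-wound list, of which 21 were in no other list, 47 in the wound-and-UVB list and 17 to 30 in the other 8. As a share of all regions above that value, they made up 5.02% in the second-wound list, 5.18% in homeostasis and 0.70% in the wound-and-UVB list. The short regions within Plxdc2 (chromosome 2, 16683004 to 16683217) and Zfp949 (chromosome 9, 88553164 to 88553380) and near Sulf1 were the strongest regions that the second-wound list gained over the first.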
